A study of Homo sapiens with 9 samples.

How the data were processed

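KOPTK1 is an established human T-cell acute lymphoblastic leukaemia (T-ALL) line. Per the labels' protocols, cells were transduced with lentivirus carrying a short hairpin RNA (shRNA), alone or with the coding region of MYC. RNA was treated with DNase, selected for poly(A), made into libraries and read from both ends for 150 bp. The submitters' processing notes name FastQC 0.11.9, HISAT2 2.2.1 and DESeq2 1.32.0 and the genome build hg38. The counting program and the gene annotation are not given in the sources used here. The values analysed are read counts per gene that the authors deposited, as whole numbers with no scaling, in 1 table of 17637 genes and 9 libraries. Its columns were joined to the samples by name, the columns named for a GFP hairpin being taken as shControl. The other columns are named for a hairpin by number alone, with or without MYC, and were taken as shDHX15_MYC and shDHX15 because the labels give no target other than DHX15. The levels of DHX15 and MYC in each library, given first in the results, bear on that join.

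Genes are identified by symbol. Of the symbols, 26 read as calendar dates and 2 stood in 2 places; these were kept under their own labels and not named. Symbols were matched to GENCODE v29 (GRCh38, the same assembly as hg38) for coordinates, length, GC content and shared sequence, and 94.9% matched. For shared sequence, 100-base windows were taken every 50 bases along each gene's transcripts, and the share also found in a gene at another locus was computed. A share of at least 0.2 is called here a gene with shared sequence, and a lower share a single-locus gene.

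The 3 groups of 3 libraries are shControl, shDHX15 and shDHX15_MYC (the same hairpin with added MYC). Total counts per library ran from 42134302 to 59688062, so that 3 counts, the limit that a count of 0 allows, correspond to 0.0503 to 0.0712 CPM (counts scaled by library size to the usual common total). Such limits cover counting error only. Genes were kept by the filterByExpr function of edgeR 4.0.16 (15309 of 17637), scaled by TMM factors and fitted with a quasi-likelihood model with 1 mean per group over all 9 libraries, in R 4.3.3. Each of the 3 comparisons was tested 2-sided, and p-values were adjusted by Benjamini and Hochberg over the 15309 genes; a gene is called changed at an adjusted p under 0.05. Fold changes are on the log2 scale with a standard error (SE), and levels are TMM-scaled CPM with the standard deviation (SD) of 3 libraries. Adjusted p-values in the results are from this edgeR model unless another test is named. Deviations from the group means did not run together in libraries of the same number (r from -0.0239 to 0.0412 across genes). The model therefore did not pair libraries by number. Whether libraries of the same number were handled together cannot be told from this.

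Before the data were examined, 34 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists hold 1110 symbols, of which 1028 matched directly, 58 matched through an older symbol and 24 did not match. Each list was compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01. This was repeated with a correlation estimated per list, and both p-values were adjusted over the 34 lists. The second form takes its degrees of freedom from the libraries, not the genes, which makes small p-values larger even at the same correlation. The rule names DHX15 and MYC, the 8 genes with the highest and the 8 with the lowest fold change of each comparison among called genes with a mean log2 CPM of at least 3 and ranges of CPM that do not overlap, and 6 genes in each direction that moved back with MYC. It also names up to 4 members of each called list with the smallest adjusted p. Names of clones and uncharacterised loci were left out, and 1 gene selected by the rule is not reported here. The same choices restricted to single-locus genes were added after the data had been examined, as were the fits on single-locus genes, on genes with a mean log2 CPM of at least 3 and on libraries thinned to equal total counts.

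Whether genes changed by the knockdown moved back with MYC was measured in 2 ways. Genes called in both comparisons with opposite directions were counted, against the number expected were the lists independent and against 20 simulations of unchanged groups that share the shDHX15 libraries. A cross-fitted slope was computed as well. In turn, the knockdown change was taken from 2 shDHX15 libraries and the MYC change from the remaining one, so that no shDHX15 library served both; the slope of the second on the first was averaged over the 3 turns.

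The steps were tested on simulated counts with the means and library sizes of these data and a set of 200 genes changed by known folds. In shDHX15 against shControl (15065 genes), 62%, 78%, 84% and 98% of genes changed 1.25, 1.5, 2 and 4-fold were recovered, and 8 unchanged genes, 4.73% of the calls, were called. In shDHX15_MYC against shDHX15 (15082 genes) the shares were 50%, 74%, 86% and 98%, with 13 unchanged genes or 7.78% of the calls. In shDHX15_MYC against shControl (15067 genes) they were 58%, 74%, 94% and 98%, with 10 unchanged genes or 5.81% of the calls. In these runs only the 200 genes changed, up or down at random. In the data, 45.0%, 84.7% and 84.5% of tested genes were called in the 3 comparisons. The simulated shares therefore do not test the scaling or the false calls where most genes change. For simulated slopes of 0, -0.5 and -1 over 15309 genes, the estimates were -0.001, -0.427 and -0.848, and -0.004, -0.486 and -0.964 among genes with a mean log2 CPM of at least 3.

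The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, size factors or total counts in place of TMM, no filter or at least 50 counts in 3 libraries, fits of only the groups compared, the replicate number as a block, fry in place of camera, and leaving out each library in turn.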

Results

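Messenger RNA was measured in 9 libraries of the T-ALL line KOPTK1, 3 each with a control hairpin (shControl), with a hairpin against the DEAH-box RNA helicase DHX15 (shDHX15) and with that hairpin and added MYC (shDHX15_MYC). The labels give the purpose as testing MYC as a downstream target of DHX15. The 3 shControl libraries held 48545616, 45672922 and 50726272 counts, the 3 shDHX15 libraries 49501577, 59688062 and 48644528, and the 3 shDHX15_MYC libraries 42434801, 43371973 and 42134302. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.9919 to 0.9925 within shControl, 0.9912 to 0.9932 within shDHX15 and 0.9949 to 0.9951 within shDHX15_MYC. Between shControl and shDHX15 it was 0.9859 to 0.9871, and between shDHX15 and shDHX15_MYC 0.9024 to 0.9046. A first principal component with 84.9% of the variance set shDHX15_MYC apart from the other libraries. Mitochondrially encoded genes took 3.93% ± 0.0589 of the counts in shControl, 3.77% ± 0.0983 in shDHX15 and 6.64% ± 0.0362 in shDHX15_MYC (SD, n = 3). The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these libraries.

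DHX15 was lower in all 3 shDHX15 libraries than in any shControl library. Its level was 280.3 ± 3.43 CPM in shControl, 167 ± 13.8 in shDHX15 and 195 ± 2.55 in shDHX15_MYC (SD, n = 3). The knockdown was thus 1.68-fold on the RNA (log2 fold change -0.75, SE 0.0441, edgeR adjusted p = 1.04e-09), and DHX15 stayed below shControl with MYC added (-0.52, SE 0.0439, adjusted p = 4.62e-09). With MYC added DHX15 was called higher than in shDHX15 (0.23, edgeR adjusted p = 1.24e-04). Under total-count scaling these changes were -0.26 against shControl and 0.43 against shDHX15. The gene lies on chromosome 4 at 24517441 to 24584550 (GRCh38, minus strand). MYC, a transcription factor that drives growth genes and lies on chromosome 8 at 127735434 to 127741434 (plus strand), was at 109 ± 0.603 CPM in shControl and 86.9 ± 3.78 in shDHX15. It fell in the knockdown by 0.33 on the log2 scale (SE 0.031, adjusted p = 2.44e-07), 1.26-fold. With the added coding region it reached 7098 ± 153 CPM, 81.6-fold above shDHX15 and 64.9-fold above shControl (adjusted p = 2.84e-24 and 5.29e-24), in all 3 libraries. The counts do not separate added from endogenous MYC, and the shDHX15_MYC libraries hold far more MYC than shControl.

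**Figure D1:**
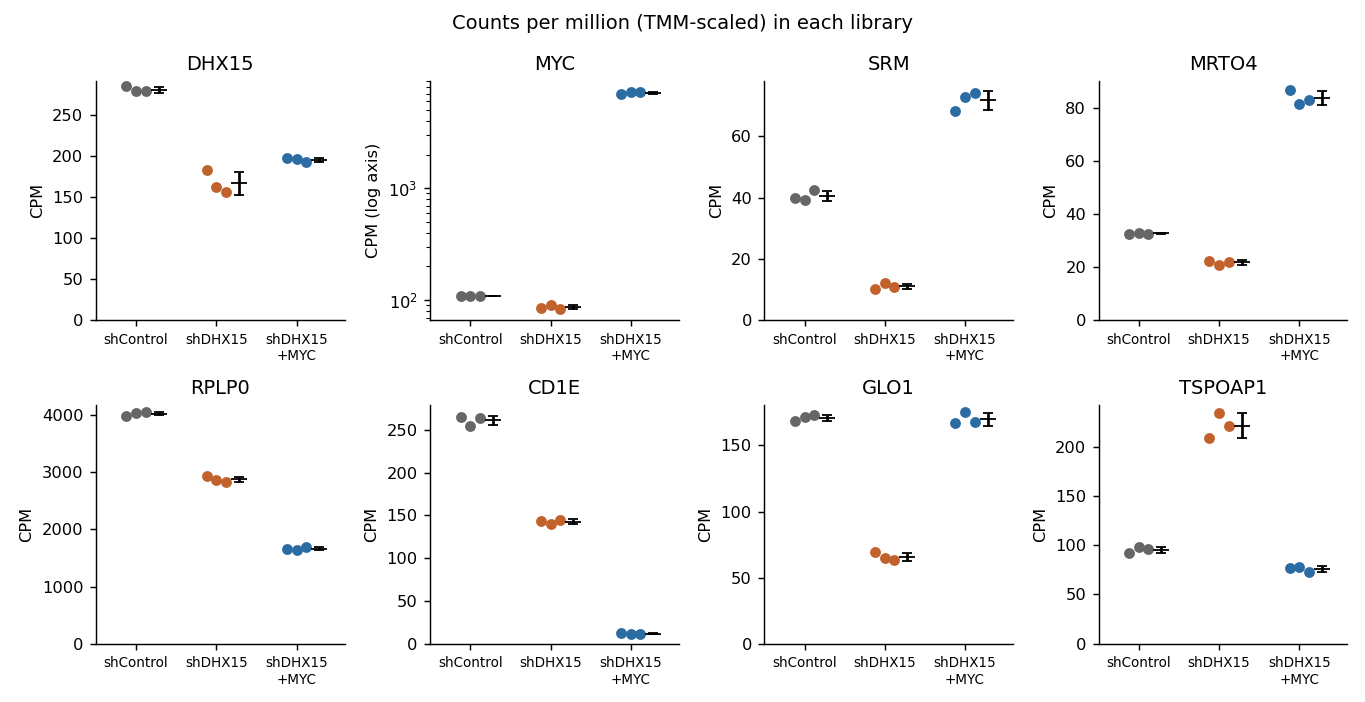
TMM-scaled CPM of 8 genes in each of the 9 libraries (points), with the mean and SD of each group (bars, n = 3); the MYC axis is logarithmic. DHX15 fell from 280.3 to 167 CPM on average with the hairpin and was at 195 with MYC added, while MYC rose to 7098.

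Against shControl, the shDHX15 libraries held less of the messages for ribosomal proteins, targets of MYC and T-cell identity genes, and more of those of mitosis. The column names give the same hairpin number for all of these libraries. Other effects of this hairpin, or different handling of the groups, cannot be told apart from loss of DHX15. The list calls came from camera with a preset correlation between genes. With an estimated correlation 0 of 34 lists were called in this comparison, also where the estimate was no higher than the preset. Most changes were small. The edgeR model called 3362 genes higher and 3524 lower of 15309 tested, with 130 and 330 of them changed at least 2-fold. Among genes with a mean log2 CPM of at least 3, a 2-fold change was called for 5 higher and 19 lower. The groups did not overlap in 51.1% of genes, where chance gives 10%. Of the 130 genes at least 2-fold higher, 101 had a mean log2 CPM under 1.

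Cytosolic ribosomal proteins fell almost as a whole in shDHX15. Of 77 measured, 76 were lower and 0 higher, with the same counts adjusted over the list alone, and the median log2 fold change was -0.50 (camera adjusted p = 6.96e-28; adjusted p = 0.317 with an estimated correlation). RPLP0 went from 4026 ± 33.0 to 2875 ± 47.7 CPM and RPS19 from 1476 ± 16.9 to 871 ± 75.5. RPL4 and RPL3 fell by 0.54 and 0.43 on the log2 scale. Among 39 translation initiation and elongation factors, 24 were lower and 6 higher (7 higher adjusted over the list alone; median -0.18, camera adjusted p = 5.54e-04; adjusted p = 0.223 with an estimated correlation). EIF3I fell from 187 ± 3.73 to 123 ± 1.68 CPM, EEF1B2 from 454 ± 11.6 to 294 ± 5.19 and EEF1G from 1309 ± 0.731 to 507 ± 5.64. EEF1G and EEF1A1, which fell by 0.38 on the log2 scale, share 0.371 and 0.339 of their windows with other loci.

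Genes that MYC is known to induce moved down together. Of 56, 37 were lower and 3 higher (39 lower adjusted over the list alone; median -0.18, camera adjusted p = 2.26e-06; adjusted p = 0.0856 with an estimated correlation). SRM, which makes the polyamine spermidine, fell 3.67-fold from 40.5 ± 1.76 to 11.01 ± 0.895 CPM (log2 fold change -1.88, SE 0.0629, adjusted p = 1.15e-12; chromosome 1, 11054584 to 11060024). MRTO4, a ribosome assembly factor, fell from 32.6 ± 0.175 to 21.7 ± 0.925 CPM, and PA2G4 and DCTPP1 fell by 0.36 and 0.49 on the log2 scale. In the list of 91 ribosome biogenesis genes, which shares 17 genes with the MYC-induced list, 50 were lower and 11 higher, also adjusted over the list alone (median -0.13, camera adjusted p = 5.54e-04; adjusted p = 0.223 with an estimated correlation). The rRNA methyltransferase FBL and NOP16 fell by 0.37 and 0.46, whereas DKC1, a pseudouridine synthase, rose by 0.39. Of 36 nucleotide and polyamine synthesis genes, 15 were lower and 5 higher (6 higher adjusted over the list alone; median -0.08, camera adjusted p = 0.0168; adjusted p = 0.152 with an estimated correlation). Total-count scaling ended that call (adjusted p = 0.0784). Its members NME1 and NME2 fell by 0.74 and 0.55, and MTHFD2, a mitochondrial folate enzyme, rose by 0.52.

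Genes that MYC is known to repress went the other way. Of 25, 13 were higher and 2 lower (14 and 3 adjusted over the list alone; median 0.17, camera adjusted p = 0.00971; adjusted p = 0.152 with an estimated correlation). TSC22D3, a glucocorticoid-induced gene, rose from 7.29 ± 0.277 to 14.7 ± 0.031 CPM, ARRDC3 from 29.2 ± 1.35 to 47.7 ± 1.65 and CCNG2 from 70.0 ± 2.22 to 87.3 ± 3.13.

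Oxidative phosphorylation, mitochondrially encoded and proteasome genes were slightly lower. Of 52 nuclear genes of oxidative phosphorylation, 34 were lower and 1 higher (37 and 2 adjusted over the list alone; median -0.21, camera adjusted p = 4.68e-06; adjusted p = 0.335 with an estimated correlation). COX6A1 fell from 251 ± 4.46 to 191 ± 12.4 CPM and ATP5O from 112 ± 3.67 to 81.7 ± 4.06. Of 13 mitochondrially encoded genes, 11 were lower and 1 higher, also adjusted over the list alone (median -0.15, camera adjusted p = 0.00374; adjusted p = 0.405 with an estimated correlation), and MT-ATP6 and MT-ND3 fell by 0.33 and 0.34. Of 34 proteasome genes, 22 were lower and 2 higher (23 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 0.00136; adjusted p = 0.427 with an estimated correlation), among them PSMC3, at 143 ± 1.95 and 105 ± 3.80 CPM.

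T-cell identity genes fell and mitotic genes rose. Of 43 T-cell identity genes, 23 were lower and 4 higher (24 and 5 adjusted over the list alone; median -0.22, camera adjusted p = 1.14e-04; adjusted p = 0.0856 with an estimated correlation). DNTT, the polymerase that adds nucleotides at V(D)J junctions, fell from 98.0 ± 2.37 to 50.01 ± 1.21 CPM. CD1E and CD1B, CD1 family genes expressed in immature thymocytes, fell from 261 ± 5.55 to 143 ± 2.93 and from 129 ± 2.55 to 72.7 ± 1.76. CD5 fell from 243 ± 3.18 to 164 ± 10.4. Of 44 genes of mitosis and G2/M, 23 were higher and 3 lower (26 and 5 adjusted over the list alone; median 0.13, camera adjusted p = 1.04e-04; adjusted p = 0.283 with an estimated correlation). The kinetochore motor CENPE rose from 24.4 ± 0.974 to 54.7 ± 4.58 CPM, CENPF from 149 ± 2.96 to 238 ± 7.89 and HMMR from 34.5 ± 1.89 to 56.1 ± 2.33. Of 32 replication-dependent histones, which end without poly(A) and were read at low levels here, 4 were higher and 0 lower (3 higher adjusted over the list alone; median 0.44, camera adjusted p = 0.0253; adjusted p = 0.318 with an estimated correlation), with HIST1H2AG at 3.49 ± 0.308 and 8.62 ± 0.628 CPM. Of 11 adherent and packaging-cell markers, 6 were lower and 0 higher, also adjusted over the list alone (median -0.56, camera adjusted p = 0.0239; adjusted p = 0.294 with an estimated correlation). The histone call was lost without replicate 1 of shControl (adjusted p = 0.0585), without replicate 1 of shDHX15 (0.0515) and with total-count scaling (0.138), and that of the adherent-cell markers without replicate 2 of shControl (0.0558). In the latter list VIM, an intermediate filament gene that T cells express too, went from 1245 ± 3.95 to 594 ± 42.2 CPM.

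Some genes outside the called lists also changed. NEFL, a neurofilament subunit, fell from 41.5 ± 0.724 to 11.3 ± 0.922 CPM, PTGIS, prostacyclin synthase, from 11.3 ± 0.799 to 3.07 ± 0.595, and FHIT from 33.8 ± 1.03 to 11.97 ± 1.20. GLO1, which detoxifies methylglyoxal, fell from 171 ± 2.41 to 65.8 ± 3.18 CPM (log2 fold change -1.38, SE 0.0384, adjusted p = 9.42e-14; chromosome 6, 38675925 to 38703141). The chaperone HSPA8 fell 2.58-fold from 2344 ± 23.5 to 910 ± 12.7 CPM (-1.37, SE 0.0243, adjusted p = 3.51e-16), and ARSB, a lysosomal sulfatase, and LIMA1 fell by 1.36 and 1.29 on the log2 scale. TSPOAP1 rose 2.32-fold from 95.4 ± 3.25 CPM in shControl (log2 fold change 1.22, SE 0.0436, adjusted p = 2.92e-12). VDAC1, the channel of the outer mitochondrial membrane, rose from 111 ± 2.54 to 229 ± 5.51, and the chromatin remodeller ATRX from 49.9 ± 0.677 to 96.7 ± 7.07. ATAD5, NLGN2 and the repressor BCL6 rose by 0.97, 0.97 and 0.94. HSPA6, with 0.261 of its windows shared, rose from 3.47 ± 0.357 to 9.25 ± 0.534 CPM. HES4 was called higher (1.47, SE 0.233), but its shDHX15 libraries held 17.7, 33.3 and 50.4 CPM against 11.8 to 12.8 in shControl.

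The other 21 of 34 lists did not pass in this comparison, with medians from -0.11 to 0.15 and camera adjusted p from 0.0559 to 0.981. Of 53 spliceosome genes 25 were lower and 10 higher, of 32 splicing DEAH helicases and G-patch partners 9 were lower and 9 higher, and of 38 SR and hnRNP splicing regulators 8 were lower and 16 higher (adjusted p = 0.0952, 0.981 and 0.069). MYC turnover regulators had 11 of 34 higher and 7 lower, DNA replication and S phase 9 of 45 higher and 10 lower, p53 targets 5 of 30 higher and 13 lower, and apoptosis regulators 8 of 30 higher and 9 lower (adjusted p = 0.78, 0.981, 0.142 and 0.677). NOTCH1 targets had 7 of 23 higher and 6 lower, cholesterol synthesis 11 of 23 higher and 4 lower, and ATF4 and integrated stress response 12 of 35 higher and 8 lower (adjusted p = 0.874, 0.0559 and 0.258). Cholesterol synthesis passed without replicate 1 of shDHX15 (adjusted p = 0.0392), with the replicate block (0.0486) and with total-count scaling (0.0406), and SR and hnRNP regulators without replicate 2 of shDHX15 (0.0344) and with total-count scaling (0.00847). The lists for heat shock chaperones, ER chaperones and the unfolded protein response, glycolysis, amino acid transport and serine and glutamine genes, interferon response, NF-kB targets, lysosome and autophagy, and B-cell, myeloid, NK and erythroid markers had adjusted p of 0.258 to 0.905. Among lists not called, median, mean and test differed in sign for heat shock, interferon, NF-kB, NOTCH1, lysosome, S phase, MYC turnover, DEAH and G-patch, B-cell and myeloid genes.

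Replicate 1 of shDHX15 stood apart, with a chi-square per degree of freedom of 18.1 and 17.1 against the other two, which gave 4.45 between them. Without it, 7566 genes were called in this comparison in place of 6886.

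**Figure D2:**
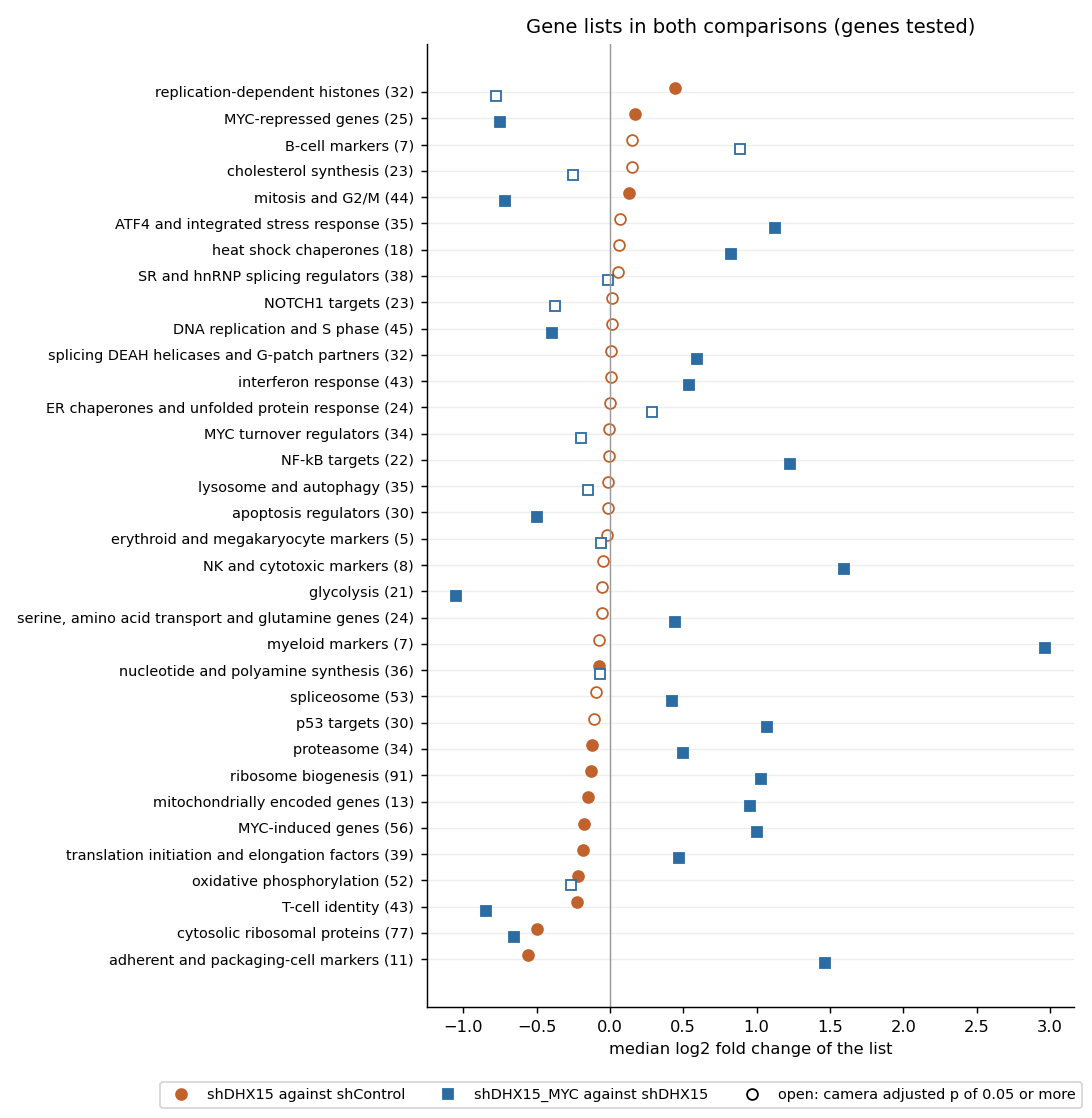
Median log2 fold change of each of the 34 gene lists (genes tested in brackets) for shDHX15 against shControl (circles) and shDHX15_MYC against shDHX15 (squares); open symbols had a camera adjusted p of 0.05 or more. Ribosome biogenesis sat at -0.13 and 1.03, ribosomal proteins at -0.50 and -0.65, and under total-count scaling neither list turned in sign.

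With MYC added, genes of ribosome biogenesis, MYC-induced genes and the ATF4 stress response rose over shDHX15, while T-cell identity, mitosis, glycolysis and ribosomal protein genes fell. With an estimated correlation the calls of mitosis, glycolysis and ribosomal proteins were lost (adjusted p = 0.0804, 0.0562 and 0.465). The model called 6438 genes higher and 6528 lower of 15309, with 3318 and 2246 at least 2-fold. Among genes with a mean log2 CPM of at least 3, 3371 were called higher and 5527 lower, 662 and 1601 of them at least 2-fold; this balance depends on the scaling, since total counts gave 4413 higher and 4505 lower, 975 and 1138 of them at least 2-fold. The groups did not overlap in 85.1% of genes, where chance gives 10%. Of the 3318 genes at least 2-fold higher, 2011 had a mean log2 CPM under 1. Genes with shared sequence were lower in the shDHX15_MYC libraries: where at least 0.8 of the windows were shared (85 genes) the median log2 fold change was -2.82, against 0.04 for the 13183 genes with no shared window. In shDHX15 against shControl these medians were 0.02 and -0.004.

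**Figure D3:**
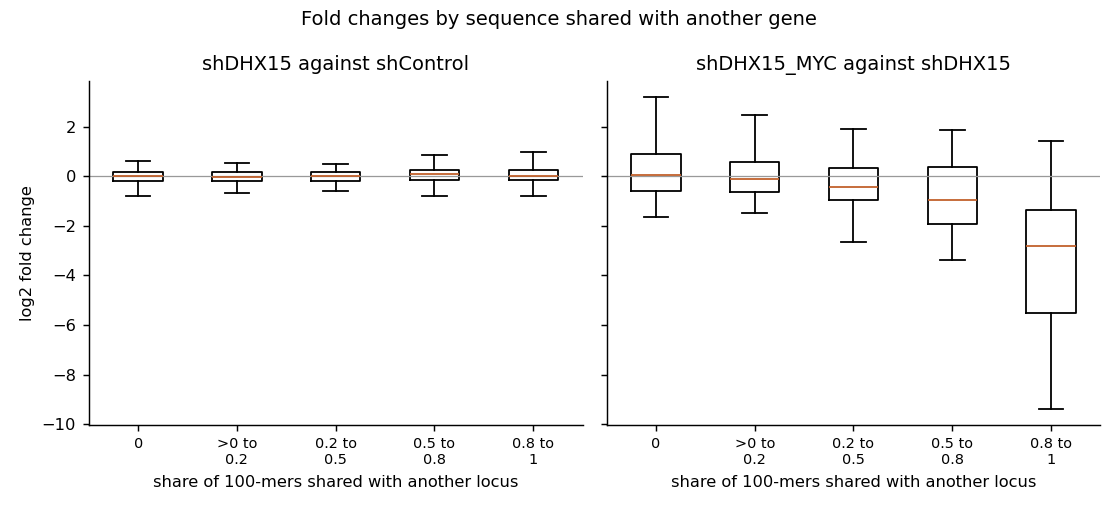
Log2 fold change of genes grouped by the share of their 100-base windows found at another locus, for the knockdown (left) and for added MYC (right); boxes hold the middle quartiles around the median and whiskers reach the 5th and 95th percentiles. The median of the genes at 0.8 to 1 is 0.02 on the left and -2.82 on the right.

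Ribosome biogenesis rose, with 84 of 91 genes higher and 7 lower, also adjusted over the list alone (median 1.03, camera adjusted p = 8.51e-15; adjusted p = 0.0195 with an estimated correlation). RRP12, which acts in the export of both ribosomal subunits, went from 30.5 ± 0.346 CPM in shDHX15 to 268 ± 3.44, the nucleolar helicase DDX21 from 113 ± 4.65 to 459 ± 9.63 and GNL2 from 41.9 ± 0.240 to 173 ± 3.02. Of 56 MYC-induced genes, 45 were higher and 7 lower (8 lower adjusted over the list alone; median 1.00, camera adjusted p = 8.60e-08; adjusted p = 0.0218 with an estimated correlation). PPRC1 and NOLC1 rose by 2.43 and 1.52 on the log2 scale, and SRM reached 71.8 ± 3.03 CPM. Of 25 MYC-repressed genes, 16 were lower and 4 higher, also adjusted over the list alone (median -0.75, camera adjusted p = 0.0331; adjusted p = 0.111 with an estimated correlation). CCNG2 fell to 10.9 ± 0.499 CPM and PIK3IP1 to 6.73 ± 0.314, but the cell cycle inhibitor CDKN1A rose from 118 ± 11.4 to 667 ± 4.73 and GADD45A, a stress-response gene, from 19.2 ± 1.94 to 125 ± 5.14.

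Stress and amino acid genes rose. Of 35 genes of ATF4 and the integrated stress response, 30 were higher and 4 lower, also adjusted over the list alone (median 1.12, camera adjusted p = 3.66e-06; adjusted p = 0.0195 with an estimated correlation). SLC3A2 and SLC7A5, which together form an amino acid transporter, rose by 2.28 and 2.08 on the log2 scale, SLC3A2 from 143 ± 3.44 to 695 ± 10.7 CPM, and PPP1R15A from 58.9 ± 2.14 to 280 ± 2.86. DDIT4, an inhibitor of mTORC1 in the same list, fell from 449 ± 1.23 to 126 ± 5.23. Of 24 serine, amino acid transport and glutamine genes, 7 of them shared with the ATF4 list, 18 were higher and 6 lower, also adjusted over the list alone (median 0.45, camera adjusted p = 0.00651; adjusted p = 0.0599 with an estimated correlation). Of 18 heat shock chaperones, 17 were higher and 1 lower, also adjusted over the list alone (median 0.82, camera adjusted p = 8.12e-06; adjusted p = 0.0599 with an estimated correlation), and HSPH1 rose from 108 ± 2.13 to 329.7 ± 7.60. Of 30 p53 targets, 20 were higher and 6 lower, also adjusted over the list alone (median 1.07, camera adjusted p = 0.0042; adjusted p = 0.0562 with an estimated correlation); the death receptor TNFRSF10B rose by 2.70 and TP53INP1 fell by 1.84. Of 22 NF-kB targets, 18 were higher and 3 lower, also adjusted over the list alone (median 1.23, camera adjusted p = 8.02e-04; adjusted p = 0.123 with an estimated correlation), and IER3 rose by 2.14.

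T-cell identity fell further, with 34 of 43 genes lower and 7 higher, also adjusted over the list alone (median -0.85, camera adjusted p = 9.97e-05; adjusted p = 0.0479 with an estimated correlation). DNTT was at 1.83 ± 0.372 CPM, CD1E at 11.9 ± 0.368 and CD1B at 7.63 ± 0.635, and the transcription factor ETS1 fell from 560.5 ± 9.83 to 188 ± 5.59. Of 77 ribosomal protein genes, 68 were lower and 3 higher, also adjusted over the list alone (median -0.65, also -0.65 in the single-locus members; camera adjusted p = 2.81e-08; adjusted p = 0.465 with an estimated correlation), and RPLP0 was at 1662 ± 23.1 CPM. Of 21 glycolysis genes, 18 were lower and 2 higher, also adjusted over the list alone (median -1.05, camera adjusted p = 2.29e-05; adjusted p = 0.0562 with an estimated correlation). PGK1 fell from 1415 ± 34.2 to 394 ± 3.28 CPM, ENO2 from 390.3 ± 6.89 to 62.5 ± 0.513 and ALDOC from 148 ± 5.14 to 12.4 ± 0.810. Of 44 mitosis and G2/M genes, 41 were lower and 2 higher, also adjusted over the list alone (median -0.72, camera adjusted p = 8.60e-08; adjusted p = 0.0804 with an estimated correlation), and CDC25B and HJURP fell by 1.73 and 0.93. Of 45 DNA replication and S phase genes, 27 were lower and 10 higher, also adjusted over the list alone (median -0.39, camera adjusted p = 0.0335; adjusted p = 0.116 with an estimated correlation); the adjusted p was 0.114 with total-count scaling. POLE fell by 0.86 and MCM7 rose by 0.74. Of 30 apoptosis regulators, 19 were lower and 8 higher, also adjusted over the list alone (median -0.50, camera adjusted p = 0.0395; adjusted p = 0.111 with an estimated correlation), and without replicate 1 of shDHX15 the adjusted p was 0.0585. The mitophagy receptors BNIP3 and BNIP3L fell from 310.1 ± 5.75 to 29.95 ± 0.897 and from 200.4 ± 6.14 to 22.2 ± 1.98.

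Proteasome genes rose in 29 of 34 and fell in 3, translation factors in 29 and 10 of 39, spliceosome genes in 38 and 12 of 53, and DEAH helicases and G-patch partners in 23 and 7 of 32, also adjusted over the list alone. Their medians were 0.50, 0.47, 0.42 and 0.59, with camera adjusted p of 1.77e-05, 0.00262, 5.12e-04 and 0.00239 and adjusted p of 0.21, 0.134, 0.111 and 0.0562 with an estimated correlation. EIF4G1, the scaffold of cap-dependent initiation, rose from 269 ± 12.3 to 882 ± 9.92 CPM, GPATCH4 from 14.96 ± 0.849 to 87.2 ± 2.32, and PSMC4 and SF3B4 by 1.16 and 1.27. Interferon response genes were higher in 29 of 43 and lower in 10, also adjusted over the list alone (median 0.54, camera adjusted p = 0.00251; adjusted p = 0.0562 with an estimated correlation), and IFI44L went from 0.467 ± 0.133 to 53.1 ± 2.08 CPM and MX1 from 5.08 ± 0.164 to 43.4 ± 1.20. Mitochondrially encoded genes were higher in 11 of 13 and lower in 0, also adjusted over the list alone (median 0.95, camera adjusted p = 8.02e-04; adjusted p = 0.229 with an estimated correlation), and MT-ND1 rose from 593 ± 15.6 to 2533 ± 44.1.

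Of 5 lists of markers of other cell types, 3 were called higher. Of their adherent-cell, NK and myeloid markers, 11 of 16, 8 of 12 and 7 of 16 passed the filter. That filter admits genes read in 1 group alone. Genes under 1 CPM in shControl rose as a group with MYC added (median log2 change 0.997). Medians of the 3 lists were 1.47, 1.59 and 2.97, but camera compared them with all genes. Whether they rose more than genes of a like level was not tested. Adherent and packaging-cell markers had 9 of 11 higher and 0 lower, NK and cytotoxic markers 6 of 8 higher and 1 lower, and myeloid markers 5 of 7 higher and 0 lower, also adjusted over the list alone. Camera gave adjusted p of 0.00609, 0.0353 and 0.0357, and adjusted p of 0.119, 0.222 and 0.176 with an estimated correlation; with total-count scaling the NK and myeloid calls ended (adjusted p = 0.0832 and 0.0732). KRT18 went from 4.46 ± 0.394 to 15.9 ± 0.587 CPM, GZMA from 3.95 ± 0.409 to 31.9 ± 1.38 and ITGAM from 0.325 ± 0.116 to 3.35 ± 0.484.

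Outside the lists, PTGIS was at 347 ± 4.96 CPM with MYC added, COL6A3, a collagen chain, went from 5.34 ± 0.579 to 90.55 ± 1.54, UCHL1, a deubiquitinase, from 8.93 ± 0.388 to 142 ± 1.59 and DNAH17 from 17.7 ± 0.605 to 253 ± 6.48. SLC6A15, TJP1 and OSM rose by 3.85, 3.81 and 3.45 on the log2 scale, and HSPA6 by 4.13. Among single-locus genes, CR2, a member of the NOTCH1 target list, fell from 114 ± 1.17 to 5.04 ± 1.03 CPM. TSHR fell from 27.4 ± 2.45 to 1.22 ± 0.227 and ARPP21 from 46.4 ± 2.05 to 2.62 ± 0.362. PPFIA4, CORO6, PLXDC1 and ADGRG1, also single-locus genes, fell by 4.14, 3.95, 3.83 and 3.81 on the log2 scale. Among genes that the naming rule admits, with a mean log2 CPM of at least 3, the 8 with the lowest fold changes all had shared sequence, so their change is uncertain. They were BOLA2B, from 79.7 ± 6.08 to 0.0494 ± 0.0330 CPM, EIF3CL, from 163 ± 5.33 to 0.583 ± 0.317, SLX1B, SULT1A4, MAGED4B, RGPD1, NAIP and FAM72C, with 0.595 to 0.981 of their windows shared, and U2AF1 in the spliceosome list (0.903) went from 83.2 ± 2.35 to 3.61 ± 0.309.

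The other 11 lists did not pass, with camera adjusted p from 0.0553 to 0.963: oxidative phosphorylation (15 of 52 higher, 33 lower), cholesterol synthesis (5 of 23 and 14), ER chaperones (15 of 24 and 8), NOTCH1 targets (8 of 23 and 14), histones (4 of 32 and 16), MYC turnover regulators (10 of 34 and 18), lysosome and autophagy (14 of 35 and 18), SR and hnRNP regulators (17 of 38 and 14), B-cell markers (3 of 7 and 2), erythroid markers (2 of 5 and 2) and nucleotide and polyamine synthesis (17 of 36 and 18). Oxidative phosphorylation passed when any 1 of 6 libraries was left out (adjusted p = 0.0327 to 0.0481). For nucleotide synthesis, SR and hnRNP, lysosome and erythroid genes, median, mean and test differed in sign. TMM factors were 1.11 to 1.12 in shDHX15_MYC and 0.969 to 0.971 in shDHX15, and scaling by total counts in their place moved the median of all genes by 0.20 in this comparison and by 0.27 in shDHX15_MYC against shControl. In neither, nor in the knockdown alone, did the median of any called list turn in sign.

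Compared with shControl, the shDHX15_MYC libraries held less of the ribosomal protein and T-cell identity messages and more of those for ribosome biogenesis. The model called 6437 genes higher and 6502 lower, with 3254 and 2223 at least 2-fold, and the groups did not overlap in 87.2% of genes, where chance gives 10%. Of these 3254, 1930 had a mean log2 CPM under 1. Among genes with a mean log2 CPM of at least 3, 3427 were called higher and 5504 lower, 664 and 1611 of them at least 2-fold, but with total-count scaling 4800 were called higher and 4118 lower, 1120 and 972 of them at least 2-fold. All 77 ribosomal protein genes were lower, also adjusted over the list alone (median -1.15, camera adjusted p = 3.03e-15; adjusted p = 0.338 with an estimated correlation). RPLP0 stood 2.42-fold below shControl, and RPS25 fell by 2.25 on the log2 scale. T-cell identity had 35 of 43 genes lower and 6 higher (36 lower adjusted over the list alone; median -1.06, camera adjusted p = 6.41e-06; adjusted p = 0.0291 with an estimated correlation), and DNTT was 53.4-fold and CD1E 21.9-fold lower. Ribosome biogenesis had 79 of 91 higher and 9 lower, MYC-induced genes 42 of 56 higher and 11 lower, and ATF4 and integrated stress response 30 of 35 higher and 3 lower, also adjusted over the list alone. Their medians were 0.95, 0.72 and 1.11, with camera adjusted p of 5.37e-13, 1.18e-05 and 1.79e-06 and adjusted p of 0.0287, 0.0413 and 0.0287 with an estimated correlation. HK2, a glycolytic member of the MYC-induced list, fell from 159 ± 6.72 CPM in shControl to 43.1 ± 2.99.

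Glycolysis (19 of 21 lower, median -1.27), mitosis and G2/M (35 of 44, -0.56), oxidative phosphorylation (36 of 52, -0.36), apoptosis regulators (21 of 30, -0.48) and S phase (31 of 45, -0.31) were lower than in shControl. Camera adjusted p were 8.48e-06, 2.60e-05, 0.00151, 0.0232 and 0.038, and adjusted p were 0.0556, 0.133, 0.39, 0.097 and 0.133 with an estimated correlation. Heat shock chaperones (16 of 18 higher, median 0.82), NF-kB targets (18 of 22, 1.08), proteasome (25 of 34, 0.36), spliceosome (36 of 53, 0.33) and DEAH and G-patch genes (24 of 32, 0.56) were higher. Camera adjusted p were 6.38e-05, 6.07e-04, 9.14e-04, 9.69e-04 and 0.00136, and adjusted p were 0.0962, 0.133, 0.338, 0.133 and 0.06 with an estimated correlation. Mitochondrially encoded (9 of 13 higher), interferon (27 of 43), p53 (21 of 30), myeloid (6 of 7) and adherent-cell genes (9 of 11) were higher too. Their camera adjusted p were 0.0101, 0.0131, 0.0131, 0.038 and 0.0483, and adjusted p were 0.364, 0.0962, 0.0962, 0.186 and 0.247 with an estimated correlation. The adherent-cell call ended without replicate 2 or 3 of shDHX15 or replicate 1 of shDHX15_MYC (adjusted p = 0.0535, 0.0546 and 0.0524), and with total-count scaling the adherent-cell, myeloid and S phase calls ended (0.139, 0.0772 and 0.184). The adherent-cell call also ended with size factors (0.0551). Here too the myeloid and adherent-cell lists were not compared with genes of a like level. Counts adjusted over the list alone were the same but for mitosis and G2/M, with 36 lower. The other 14 lists did not pass, with camera adjusted p from 0.0512 to 0.878. Serine, amino acid transport and glutamine genes (15 of 24 higher; adjusted p = 0.0512) passed without replicate 1 of shDHX15 (0.0472), without replicate 1 or 3 of shDHX15_MYC (0.0483 each), with size factors (0.0498), with total-count scaling (0.0381) and among single-locus genes (0.0468). MYC-repressed genes and translation factors passed with total-count scaling (0.0404 and 0.048) and among single-locus genes (0.0451 and 0.0169), and SR and hnRNP regulators with total-count scaling (0.0233). For lysosome and autophagy, median and mean differed in sign.

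Genes changed by the knockdown more often moved back than on when MYC was added. Of the 3524 lower genes, 1774 (50.3%) were called higher with MYC, where 1482 would be expected from independent lists, and 1357 were called lower again. Of the 3362 higher genes, 2016 (59.96%) were called lower, where 1433.6 would be expected, and 931 were called higher again. Both comparisons use the shDHX15 libraries, so part of the excess may come from sharing them. In 20 simulations of unchanged groups that share them 0 genes reversed, but these called only 0.45 and 0.5 genes on average, so that count says little. Over all tested genes, 57.68% changed in opposite directions and the correlation of the changes was -0.338, both nearer to no relation than the simulated means of 66.54% and -0.491. The covariance was -0.278 against a simulated -0.0148, and -0.0413 against -0.00198 among genes with a mean log2 CPM of at least 3. The cross-fitted slope was -0.85 (-0.79, -0.89 and -0.88 in the 3 turns), with 59.7% of the genes changing in the opposite direction, and among genes with a mean log2 CPM of at least 3 it was -0.53 (-0.57 to -0.46), with 58.1%. A simulated full return gave -0.848 and -0.964, but with changes alike in both directions. In these data the slope was -1.191 over genes called lower and -0.272 over genes called higher. The simulated values therefore do not show that the return was full here. Across genes the changes were loosely related, with a mean r of -0.36 over the 3 turns. It was -0.20 among genes with a mean log2 CPM of at least 3. Return to shControl was less common than passing it. Of the reversed genes, 359 lower and 349 higher ones were not called against shControl, while 1294 and 1526 were called on the other side. Of all 3524 lower genes, 1815 were called below shControl with MYC added, where 1496.7 would be expected from independent lists. Of the 3362 higher genes, 1431 were called above it, where 1413.6 would be expected. In all, 415 and 405 were not called against shControl. These comparisons share the shControl libraries, which may add to the counts.

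Among the strongest reversed genes, GLO1 was at 169.8 ± 4.72 CPM with MYC against 171 in shControl (log2 fold change -0.01, SE 0.0369, adjusted p = 0.793; 0.25 under total-count scaling), and DUSP6, a phosphatase of ERK, at 240.1, 102 and 250.0 CPM in shControl, shDHX15 and shDHX15_MYC. SRM, PTGIS and NABP2, a single-strand DNA binding protein, passed their shControl levels. NEFL reached 28.4 ± 0.317 CPM and stayed below. TSPOAP1, NLGN2, BCL6, PGM2L1, KANK2 and MCAM rose in the knockdown and fell below shControl with MYC, BCL6 to 9.78 ± 0.167 CPM and PGM2L1 from 59.7 ± 2.41 to 16.4 ± 0.349. Other genes lowered by the knockdown were also below shControl with MYC added. VIM was at 609 ± 11.7 CPM (log2 fold change from shControl -1.03), CD5 at 165 (-0.56) and FHIT at 4.95 ± 0.630 (-2.77).

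**Figure D4:**
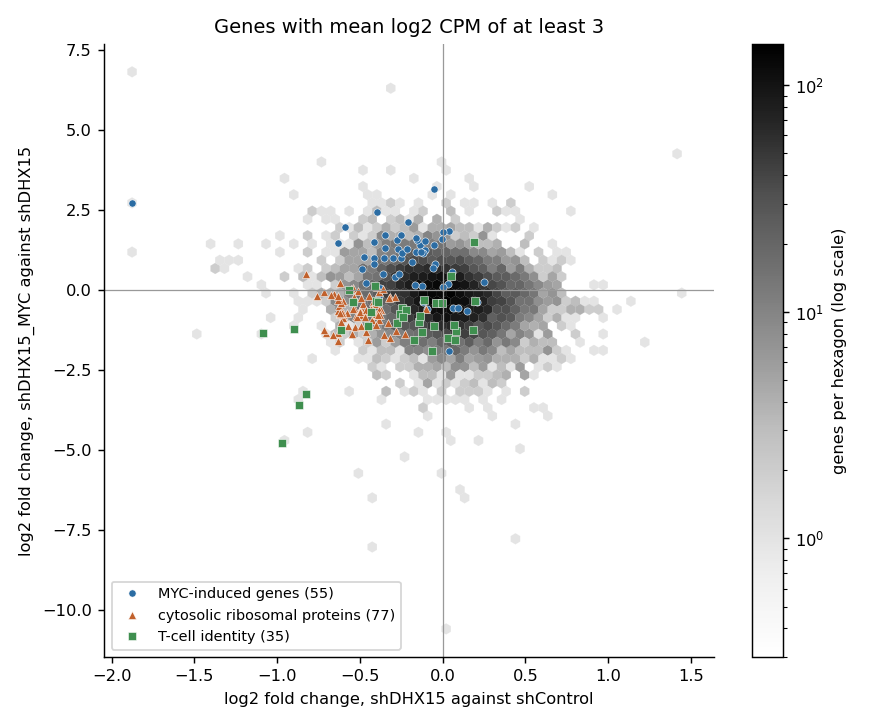
Log2 fold change of each gene with a mean log2 CPM of at least 3 in shDHX15 against shControl (x axis) and shDHX15_MYC against shDHX15 (y axis), as hexagons shaded by the number of genes, with the members of 3 lists as points. Of 37 MYC-induced genes lower in the knockdown, 34 were higher with MYC, against 3 of 76 ribosomal protein genes and 1 of 23 T-cell identity genes; the plot holds members with a mean log2 CPM of at least 3.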

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

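The alternatives on single-locus genes, on genes with a mean log2 CPM of at least 3 (with each scaling) and on thinned libraries, the slope with GC and length trends removed and the split of simulated genes by level were chosen after the data had been examined; the others were planned. Across tools, filters, size factors, fits of only the groups compared, the replicate block and thinning, the knockdown comparison called 6283 to 6882 genes, the addition of MYC 11827 to 13329 and the comparison with shControl 11898 to 13226; total-count scaling gave 7144, 13027 and 13021, and single-locus genes alone 6433, 12008 and 11975. Leaving out each library in turn gave 5958 to 7566, 12635 to 13144 and 12543 to 13346 genes, 3303 to 4200 reversed genes, 12 to 14, 22 to 24 and 19 to 21 gene lists. Slopes were -0.844 to -0.798 without each shControl or shDHX15_MYC library; it was not run without a shDHX15 library. DHX15 then ranged from -0.82 to -0.70 in the knockdown and MYC from -0.37 to -0.31. With the replicate block, the counts were 6748, 12904 and 12851. Of the genes that the rule selected in a comparison, each counted in that comparison alone, 69 of 70 in the knockdown, 119 of 119 with MYC added and 98 of 98 against shControl stayed called in the same direction in those of the 20 settings that tested them, since a setting restricted to some genes leaves out the others; the exception is HIST1H2BH.

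Total-count scaling raised the share of higher calls from 48.8% to 64.0% in the knockdown, from 49.6% to 59.0% with MYC added and from 49.7% to 62.4% against shControl. Under it, log2 fold changes turned to 0.0188 for RPS19 and 0.112 for MTHFD2 with MYC added, and against shControl to 0.255 for GLO1, 0.230 for HMMR, 0.0219 for NME2, 0.0961 for COX6A1, 0.0494 for UQCRH, 0.101 for FBL and 0.0216 for NOP16; with TMM these genes' changes in these comparisons, from -0.2435 to -0.0106, were smaller than the shift of all genes in the same comparison. With MYC added, HES4 ranged from -0.353 to 0.347 and CD5 from -0.058 to 0.0382 when 1 library was left out, HES4 being positive without replicate 3 of shDHX15 and CD5 negative without replicate 1; neither was called with all libraries.

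With an estimated correlation camera called 0 lists in the knockdown, 4 with MYC added (ribosome biogenesis, ATF4, MYC-induced and T-cell identity) and 4 against shControl (the same 4 names). The estimate was 0.785 among ribosomal proteins. In the knockdown, calls were also lost where it was at the preset 0.01, as for T-cell identity, or under it, as for MYC-repressed genes (-0.011). A correlation above the preset cannot account for these losses. With an estimated correlation, camera also takes its degrees of freedom from the few libraries, not from the genes. For T-cell identity in the knockdown, camera p before adjustment was 1.67e-05 with the preset and 0.00503 with the estimate of 0.01. A call lost in this way is therefore not in itself a sign of correlation between genes. The directional test of fry, which does not compare a list with other genes, called 25 lists in the knockdown and 32 against shControl, and its mixed test 33 and 34. Its direction was opposite for heat shock chaperones in the knockdown (adjusted p = 4.53e-04) and, with MYC added, for nucleotide and polyamine synthesis (adjusted p = 6.85e-05) and SR and hnRNP regulators (adjusted p = 0.0448), lists whose members went both ways.

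The return slope was -0.768 with total-count scaling, -0.923 with at least 50 counts in 3 libraries, -0.533 among genes with a mean log2 CPM of at least 3 and -0.702 among these with GC and length trends removed. It was -1.191 over genes called lower and -0.272 over genes called higher. The cause of these differences was not tested. Low counts limit the genes near the floor: of simulated 2-fold changes in the knockdown, 3 of 11 were recovered under a mean log2 CPM of 1 and 32 of 32 at 3 or more, and with MYC added 4 of 11 and 29 of 29.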

Other observations

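Of the tests in this part, those of depth and of GC content and length were set before their results were seen, and all others after. The list-by-list account of what moved back is a hypothesis of this kind. Of the 37 MYC-induced genes that were lower in the knockdown, 34 (91.9%) were called higher when MYC was added, against 49.9% of the other lower genes (Fisher's exact test over 34 lists, 2-sided, adjusted p = 1.25e-06). Of 50 ribosome biogenesis genes that were lower, 45 (90%) were called higher, against 49.8% (adjusted p = 5.93e-08). For 22 proteasome genes, 24 translation factors and 8 genes of the ATF4 list, 18, 19 and 8 were called higher (adjusted p = 0.0289, 0.0366 and 0.0377). Of genes that the knockdown had raised, 1 of 11 in ribosome biogenesis and 2 of 12 in the ATF4 list were called lower with MYC, against 60.1% of other raised genes (adjusted p = 0.00824 and 0.0418), so these lists rose with MYC whichever way the knockdown had moved their genes. Genes are not independent replicates, so these p-values overstate the certainty. Most of these genes passed their control level: 31 of the 37 MYC-induced and 40 of the 50 ribosome biogenesis genes were called above shControl.

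In 2 other lists lowered by the knockdown, few genes came back. Of 76 ribosomal protein genes that were lower, 3 (3.9%) were called higher with MYC added, against 51.4% of other lower genes (adjusted p = 1.11e-17), and all 76 were called below shControl. Of 23 T-cell identity genes, 1 (4.3%) was called higher, against 50.6% (adjusted p = 2.09e-05), and all 23 were called below shControl. Of 11 mitochondrially encoded genes, 15 of nucleotide and polyamine synthesis, 6 adherent-cell markers and 34 of oxidative phosphorylation that were lower, 9, 10, 4 and 12 were called higher (adjusted p = 0.184, 0.465, 0.865 and 0.225). Of the 23 mitosis and G2/M genes that the knockdown raised, 22 were called lower with MYC (Fisher's exact adjusted p = 0.00534). This list fell as a whole with MYC, with 41 of 44 genes lower. Of its 3 genes lower in the knockdown, 0 were called higher, so it fell whichever way the knockdown had moved its genes. Of 8 heat shock chaperones that the knockdown raised, 0 were called lower with MYC (Fisher's exact adjusted p = 0.00824). Of 13 MYC-repressed genes it raised, 9 were called lower with MYC, against 59.9% of other raised genes. That difference was not called (Fisher's exact p = 0.581 before adjustment). In these libraries, then, messages for building ribosomes rose with MYC while those for the ribosomal proteins themselves were lower than in either other group. With an estimated correlation the ribosomal protein list was not called with MYC added (camera adjusted p = 0.465). The windows count exact matches only, so different counting of reads from similar genes is not excluded as a part of that fall.

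Genes changed by the knockdown moved back with MYC added, and a candidate technical source is that both comparisons use the same shDHX15 libraries. With no shDHX15 library in both, the slope was -0.852, between -0.887 and -0.791 in the 3 turns, which argues against shared noise. With GC and length trends removed it was -0.702 among genes with a mean log2 CPM of at least 3, where it was -0.533 before, which argues against these trends as the whole source. A response to MYC may account for the 91.9% of MYC-induced genes lower in the knockdown that were called higher with MYC added. Most of these passed their shControl level. MYC-repressed genes raised by the knockdown were not called as moving back more often than other genes. Such a response cannot be told apart from different handling of the shDHX15 group as a whole, since each group holds its own 3 libraries. No group had added MYC with the control hairpin. Changes that MYC makes regardless of the knockdown therefore cannot be told apart from a reversal of the knockdown. MYC also stood far above its control level, so the return does not measure a rescue at normal MYC. DHX15 itself was higher in shDHX15_MYC than in shDHX15 (log2 fold change 0.23). A weaker knockdown in these libraries may account for part of the return, which was not tested.

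Genes with near-identical copies were lower in the shDHX15_MYC libraries, and 1 explanation is that reads matching more than 1 gene were counted differently in these libraries. The 85 genes sharing at least 0.8 of their windows were matched to genes with no copies by mean level over all 9 libraries. Their median lay 3.28 log2 units below that of the matched genes (difference -3.278). With all libraries thinned to equal total counts the difference was -3.201, which argues against the difference in totals. The mean level includes the shDHX15_MYC libraries, where the copies were low, which may enlarge the difference. The matched genes had an average median of 0.462, against 0.037 for all genes with no shared window. Of the 85 genes, 67.06% had a log2 fold change below -2, against at most 10.6% in 1000 matched draws, which argues against a response to MYC unrelated to shared sequence. In 36 pairs of copies, some of which share a member, the log2 change of the sum over both had a median of -2.838 and was -1 or lower in 29, so in these 29 reads did not merely pass from one copy to its partner. For EIF3CL and EIF3C, which went from 162.7 to 0.583 and from 122.9 to 278.3 CPM, the sum changed by only -0.034. Different read assignment may thus account for most of this pattern, and comparisons with the shDHX15_MYC libraries may carry other differences in processing between groups.

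Genes near the detection floor were higher with MYC added. For the 5002 genes under 1 CPM in shControl, the median log2 change was 0.997 with MYC and -0.043 in the knockdown; it was 0.959 in libraries thinned to equal total counts, which argues against the difference in totals. Traces of genomic DNA, which could add reads to silent genes, would add more to longer genes; the added CPM had a Spearman rho of 0.238 with exon length across genes, which does not decide, since the bound for this test was moved after its value was seen, and the labels' protocols include a DNase step. Among the 4322 genes with no shared window, which make up most of these genes, the median was 1.083. The rise was thus not confined to genes with copies. A response of the cells to MYC and a difference between library groups cannot be told apart here, because the labels give no batches and each group holds its own libraries.

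Each comparison sets 3 libraries against 3, which can be split in 10 ways, too few for a share under 0.05. In the fits of 2 groups the real split was the 1 of 10 with the most genes in each comparison: 6283 in the knockdown, 12805 with MYC added and 13226 against shControl. The highest of the other splits called 0 genes in each by edgeR and by limma-voom, and 421, 9 and 9 at an unadjusted p under 0.05. Every other split mixes libraries of both groups, so a real difference widens its spread and few calls follow. The low counts of these splits are therefore no measure of calls between unchanged groups.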
